A study of Micropterus salmoides with 16 samples.

How the data were processed

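RNA from liver and gonad of largemouth bass (Micropterus salmoides) was hybridised to 16 custom Agilent arrays with 2 colours. Each array carried Cy5-labelled RNA of 1 organ of 1 fish and a Cy3-labelled reference pool, with the same dye orientation throughout, per the labels. The fish had been exposed for 48 h to E2 (estradiol, an estrogen, in common usage, since the labels give only the abbreviation) or to the vehicle. The labels call the samples biological replicates, with 4 fish per treatment. Groups and replicate numbers came from the sample titles. The description of 1 sample, E2 gonad 1, gives another replicate number than its title, and the title was used. The sex of the fish, the dose, the route and the make-up of the reference pool were not given in the sources used here.

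The deposited scanner files hold intensity values, made with Agilent Feature Extraction 9.5 per the submitters' processing notes. Per the file headers, the processed intensity columns had been background-subtracted with spatial detrending and dye-normalised by a linear and a lowess step, while the mean and background intensity columns had not. The log10 ratio column of the deposited scanner files is the ratio of those processed signals, Cy5 over Cy3. The spot marks of the deposited files (well above background, outlier, saturated) are 0 or 1, set by the scanner software per the file headers. The deposited value table of the whole series holds log2 ratios as far as its values show: each column rose by 3.24 to 3.31 per unit of that array's log10 ratio, with the same sign. Its scale is inferred from that slope and its direction from the sign. Its column medians lay between -0.07 and 0.29, and whether the authors centred it is not stated. It held 29661 of the 33514 probes and served as an alternative only.

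Each array held 45220 spots, of which 43803 were not control spots. They represented 33514 probes of 60 bases, 10289 of them on 2 spots. The median Cy5 signal per array lay between 153 and 339 on slides 1 and 2 and between 73.5 and 102 on slides 3 and 4. The median Cy3 signal lay between 251 and 300 on every array. Between 49.7% and 79.4% of spots were well above background in Cy5. No pair of arrays held identical values, and the highest correlation between different arrays was 0.972. The number of arrays limits the precision of every value.

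Mean signals were corrected with normexp (offset 50) on the local background median, normalised within each array by loess with control spots at weight 0, and averaged over the spots of a probe. R 4.3.3 and limma 3.58.1 were used. Spots marked as non-uniformity outliers, of the spot or of its background, were left out before the background fit. This choice departs from the first run and was made after its results and fits had been seen. In the first run only spots marked themselves were left out, and only after the background fit. Between 2 and 9 spots on 6 arrays then lay far below the rest after subtraction, all marked by the scanner software for their background, and they set the fit of the whole array. On E2 gonad 1, for example, the fitted Cy5 background had a mean of -876 with those spots and -3.21 without them. The results of the first run are given with the other alternatives.

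A probe was tested where it was well above background in Cy5 on at least 3 of the 4 arrays of at least 1 group in the fit and lacked a value on at most 2 arrays. Groups were compared on log2 ratios with limma (lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the probes tested, at 0.05. E2 was compared with control within liver and within gonad, using the arrays of that organ. The difference of the E2 effect between the organs was tested as an interaction over all 16 arrays. Control liver was compared with control gonad. These designs and most alternatives were fixed before the data were examined. Errors of limma fold changes are SE and intervals are 95% confidence intervals, while group means are given with SD.

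A bound was given where a probe was not well above background on any array of a group: the brighter group's mean Cy5 value against, per array of the dimmer group, the higher of the lowest signal well above background and the probe's own, after loess and Aquantile, which is open to dye bias without swapped dyes.

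The files pair probes with contig names and no gene names, and 0 of the contig names were found in the RefSeq gene table used. The 28 gene lists planned before the data were examined, cell type markers included, could therefore not be applied, nor could the planned list tests or the part of the naming rule that asked for known estrogen-responsive genes. The rule for single probes was kept without its annotation criterion, an adaptation made after the files were seen. It took probes past the threshold whose groups did not overlap, 1 per contig and the brightest of it, ordered by size. Where fewer than 6 passed, those with the smallest raw p were taken. At most 2 probes that rose and 2 that fell are named per comparison. Probes are of 4 classes by their IDs (AF, AM, CF, CM), and the contig names of nearly all AM and of all CM probes carry the word minus in the files.

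Arrays with the same replicate number shared a slide and a scan day, as the scanner files show, and each of the 4 slides held 1 array of every group. The block by replicate number is therefore also the slide block, and a separate block by scan day was not run because it could not be separated from the slide. Deviations from the group means correlated between same-numbered arrays in every pair, with r from 0.106 to 0.560 for the liver groups and from 0.334 to 0.517 for the gonad groups, so the numbers pair the arrays in both E2 comparisons. For control liver and control gonad r lay between 0.0382 and 0.168, and the rule of over 0.1 in every pair was not met. Fold changes within 1 slide set 1 array against 1.

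Organ-predominant probe sets were defined after the data were examined, from all livers against all gonads, with E2 and control arrays weighted equally, at an adjusted p under 0.05 and more than 2 on the log2 scale. The liver-predominant set held 1154 probes of 811 contigs and the gonad-predominant set 710 probes of 578 contigs. The median log2 ratio of a set on each array was compared between E2 and control with exact two-sided permutation tests, for which 4 against 4 arrays allow a smallest p of 0.0286.

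The pipeline was tested on simulated data with the spread of each comparison, in which 100 probes changed 2-fold and 100 changed 4-fold. Simulated errors were independent between probes and arrays, so slide effects and correlated probes were not represented. The shares recovered apply to that number of changed probes and may be lower where fewer change. For E2 in liver, 23% of the 2-fold and 72% of the 4-fold changes were recovered among 17309 probes, with 8 unchanged probes called. For E2 in gonad the shares were 61% and 96% among 18717 probes, with 6 called. For the difference between organs they were 17% and 74% among 19648 probes, with 5 called. For control liver against control gonad they were 48% and 87% among 19322 probes, with 6 called.

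Alternatives covered the background correction, the normalisation, the filter, the value table, the Cy5 channel alone, the slide block, the samples in the fit, the variance model, array weights, the mean over probes of 1 contig name, each replicate left out, the treatment of marked spots, and slides 1 and 2 or slides 3 and 4 alone.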

Results

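Transcript levels were measured in liver and gonad of largemouth bass, a freshwater fish, after 48 h of exposure to E2 or to the vehicle alone. The 4 groups were control liver, E2 liver, control gonad and E2 gonad, with 4 arrays each. A log2 ratio above 0 means a higher signal in the sample (Cy5) than in the reference pool (Cy3) at that probe. Arrays of 1 organ resembled each other more than arrays of different organs. Across probes, r lay between 0.655 and 0.972 among livers, between 0.900 and 0.966 among gonads, and between 0.207 and 0.564 between a liver and a gonad. Livers of E2 fish varied more than the other groups, with a median SD of the log2 ratio of 0.39 per probe, against 0.29 in control liver, 0.25 in control gonad and 0.22 in E2 gonad. Among E2 livers, pairs with E2 liver 3 correlated at 0.661 to 0.749 and the other pairs at 0.838 to 0.844. Pairs of control livers lay between 0.847 and 0.972, so a wider spread is not shown for every E2 liver. The Cy3 reference varied less, with a median SD between 0.08 and 0.10 in every group. Because the files give contigs without gene names, transcripts are identified by probe and contig.

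The comparison of control liver with control gonad described how the organs differ without exposure. Of 19681 probes tested, 6820 were higher in liver and 4578 were lower (limma, Benjamini-Hochberg 0.05, n = 4 per organ), together 57.9%. Differences above 16-fold were mostly in the direction of liver, at 451 probes against 38. The largest liver excess named by the rule was at UF_Msa_AF_109131, with a log2 difference of 8.82 ± 0.71 (SE, limma adjusted p = 5.04e-06). Its log2 ratio averaged 2.16 ± 1.80 in control liver and -6.66 ± 0.16 in control gonad (SD, n = 4). The other probes of that contig differed in the same direction, by 2.90 and 6.82. UF_Msa_CF_119697 (contig28778) was higher in liver by 7.83 ± 0.54 (SE, limma adjusted p = 1.75e-06). Among probes lower in liver, UF_Msa_AF_108720 differed by -5.78 ± 0.56 (SE, limma adjusted p = 1.80e-05), and the other probes of its contig by -6.43 and -0.88. UF_Msa_AM_112654 (contig24954) differed by -4.95 ± 0.25 (SE, limma adjusted p = 2.11e-07), while the other probes of its contig differed by -1.15 and -0.83.

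Within the 4 slides, the differences between control organs ranged from 6.17 to 10.81 at UF_Msa_AF_109131, from 5.43 to 8.80 at UF_Msa_CF_119697, from -7.69 to -4.54 at UF_Msa_AF_108720 and from -5.51 to -4.30 at UF_Msa_AM_112654. With the slide as a block, 7126 probes were higher in liver and 4622 lower. Pairs of slides gave closely similar fold changes, with r across probes between 0.858 and 0.951. The balance of higher to lower probes moved with the scaling. In liver, 59.8% of the differing probes were higher with loess, 48.1% with the processed signals, 48.3% in the value table, 46.4% with Cy5 alone and 25.1% with median centring (1431 higher and 4260 lower). The median of all log2 differences was 0.19 with loess and -0.29 with median centring, so a direction is relative to that shift.

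Exposure to E2 was compared with the vehicle in liver to find transcripts that changed there. A single probe rose and a single probe fell among 17660 tested (limma, Benjamini-Hochberg 0.05, n = 4 per group). UF_Msa_AF_109886 (contig LMB_S454.sd.85.C1, probe sequence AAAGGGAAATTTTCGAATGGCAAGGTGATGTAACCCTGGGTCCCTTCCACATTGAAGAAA) rose by 5.44 ± 0.47 on the log2 scale (SE, interval 4.35 to 6.53, limma adjusted p = 0.0474), which is 43.3-fold. Part of this ratio came from a lower Cy3 reference signal on the E2 livers, and with Cy5 alone the log2 change was 4.40 (limma adjusted p = 0.0271). Its log2 ratio averaged -5.02 ± 0.37 in control liver and 0.42 ± 0.92 in E2 liver (SD, n = 3 each). UF_Msa_AM_116619 (contig24015, probe sequence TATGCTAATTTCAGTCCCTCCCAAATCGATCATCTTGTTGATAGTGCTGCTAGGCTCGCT) fell by 2.71 ± 0.25 (SE, interval -3.27 to -2.14, limma adjusted p = 0.0258), which is 6.52-fold, from 2.45 ± 0.43 in control liver to -0.25 ± 0.26 in E2 liver (SD, n = 4). Neither call held with the slide as a block, where 0 probes passed (limma, 2984 at an unadjusted p under 0.05) and both had an adjusted p of 0.187.

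Other probes of the same contigs behaved differently for the 2 transcripts. On contig LMB_S454.sd.85.C1, 2 further probes had log2 changes of 3.59 ± 0.78 and 2.28 ± 0.83 (SE), with limma adjusted p of 0.213 and 0.281. On contig24015, 2 further probes, of the AF class and without the word minus in their names, had log2 changes of -0.29 and -0.26. UF_Msa_AF_109886 lacked a value on E2 liver 3 and control liver 1, where its spots had been marked as outliers. On E2 liver 3 those spots had Cy5 signals of 12229 and 9627, against 2698 and 2362 in the control liver of the same slide. E2 liver 1, 2 and 4 had signals between 101021 and 376724. The control livers of their slides had signals between 21741 and 26668 on slides 1 and 2, and of 3009 and 2268 on slide 4. Raw signals of different slides therefore do not compare directly. Relative to the array median, with marked spots kept, the log2 change in Cy5 was 4.20, 3.28, 2.01 and 5.35 on slides 1 to 4. With the marked spots kept in the averages, the log2 change was 4.58 and the limma adjusted p 0.210.

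**Figure D1:**
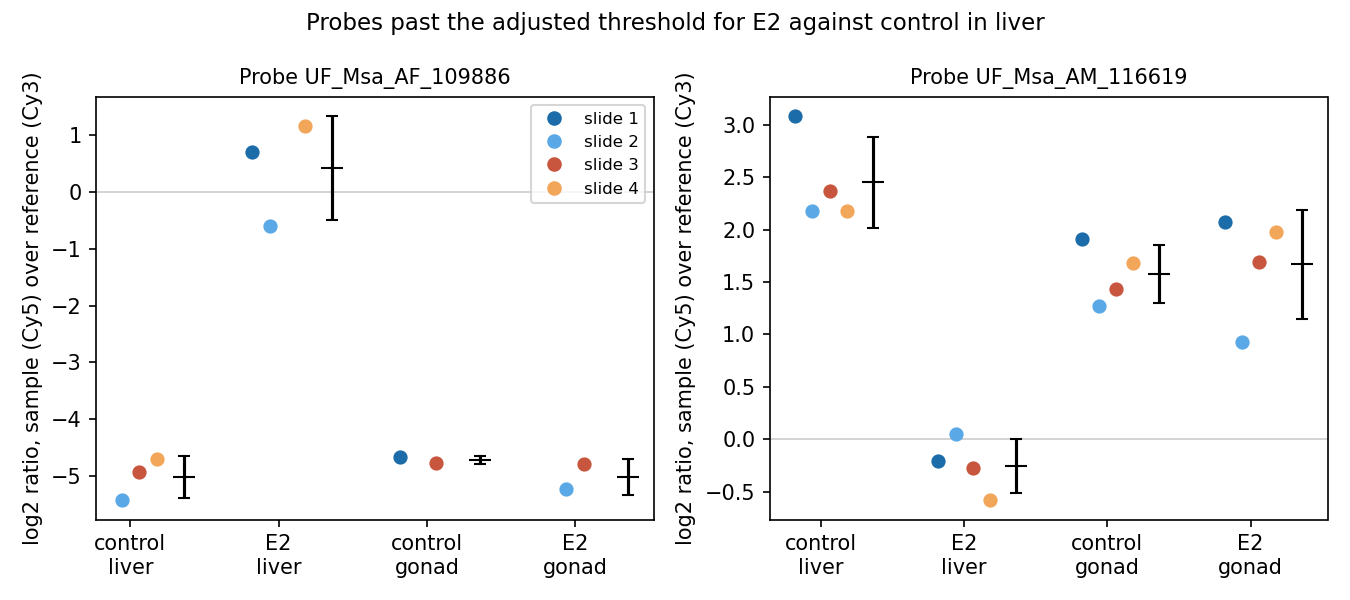
Log2 ratio of sample (Cy5) over reference pool (Cy3) at UF_Msa_AF_109886 (left) and UF_Msa_AM_116619 (right) by group. Each point is 1 array coloured by slide, horizontal marks are group means and bars are SD. UF_Msa_AF_109886 averaged 0.42 in E2 liver and -5.02 in control liver, and UF_Msa_AM_116619 averaged -0.25 in E2 liver and 2.45 in control liver.

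The log2 changes within slides were 4.82 on slide 2 and 5.86 on slide 4 for UF_Msa_AF_109886, with no value on the others. For UF_Msa_AM_116619 they were -3.29, -2.13, -2.64 and -2.76 on slides 1 to 4. UF_Msa_AF_102449 (contig04065) had a log2 change of 1.76 ± 0.27 (SE, limma adjusted p = 0.213), with 1.57, 1.98, 1.69 and 1.80 within slides and 3.17 with the processed signals. UF_Msa_CM_135824 (contig27443) had a log2 change of -2.0 ± 0.27 (SE, limma adjusted p = 0.187), with -1.60, -1.78, -2.73 and -1.89 within slides, and the other probes of its contig had -0.63 and -0.75. Neither passed the threshold. The count rose to 1296 with array quality weights, to 721 with all 16 arrays in 1 fit, to 142 without control liver 4 (16 higher and 126 lower), to 49 without E2 liver 3 (41 higher and 8 lower) and to 22 without E2 liver 2 (2 higher and 20 lower). The prevailing direction differed with the array left out. The count was 0 with median centring, without the filter, and without control liver 2, control liver 3, E2 liver 1 or E2 liver 4.

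Below the threshold, changes in liver were shared between most pairs of slides, but not between slides 3 and 4. At an unadjusted p under 0.05 there were 2500 probes (14.2%), against 883 expected by chance. A log2 change beyond 1 was seen at 377 probes upward and 789 downward. The sign was the same on all 4 slides at 27.1% of probes, against 12.5% by chance, and the 4 arrays of each group did not overlap at 7.17%, against 2.86% by chance. Single slides gave fold changes that correlated across probes at r between 0.258 and 0.492 in 5 of the 6 pairs and at -0.011 for slides 3 and 4. Means over 2 slides correlated at 0.606 (slides 1 and 2 with 3 and 4), 0.542 (1 and 3 with 2 and 4) and 0.323 (1 and 4 with 2 and 3). Probes are not independent replicates, so the values expected by chance are averages without a spread. Of the 35 splits of the 8 livers, 3 gave at least 2500 probes at that level, the real one included, and the highest other gave 4302. Among the 8 splits that part every slide, too few for a share under 0.05, the highest other gave 1140. Where a contig had a pair of AF or CF probes, the first of them beyond 2-fold had a partner with the same sign in 251 of 256 cases.

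Liver-predominant probes as a group had lower values in E2 liver on every slide in the reported fit, without passing the exact test over arrays. Their median log2 ratio averaged 0.99 ± 0.85 in E2 liver and 1.77 ± 0.49 in control liver (SD, n = 4), a difference of -0.77 (exact permutation p = 0.143, Benjamini-Hochberg adjusted 0.571 over 4 tests). The difference was -0.49, -0.56, -1.94 and -0.12 on slides 1 to 4, with all 4 slides lower in the reported fit. The sign on slide 4 depended on the scaling. There the medians of E2 liver and control liver were -0.034 and -0.055 with median centring, and 10.94 and 10.91 with Cy5 alone. In the reported fit the exact paired permutation over slides gave p = 0.125, the smallest that 4 slides allow, so that test could not pass. Of the 1154 probes, 368 were lower and 68 higher at an unadjusted p under 0.05, and 77.7% had a log2 change below 0. E2 liver 3 had the lowest median, -0.21, where the other livers lay between 0.97 and 2.15, and without it the difference was -0.37. Gonad-predominant probes differed by 0.01 in liver (exact permutation p = 0.943, n = 4).

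**Figure D2:**
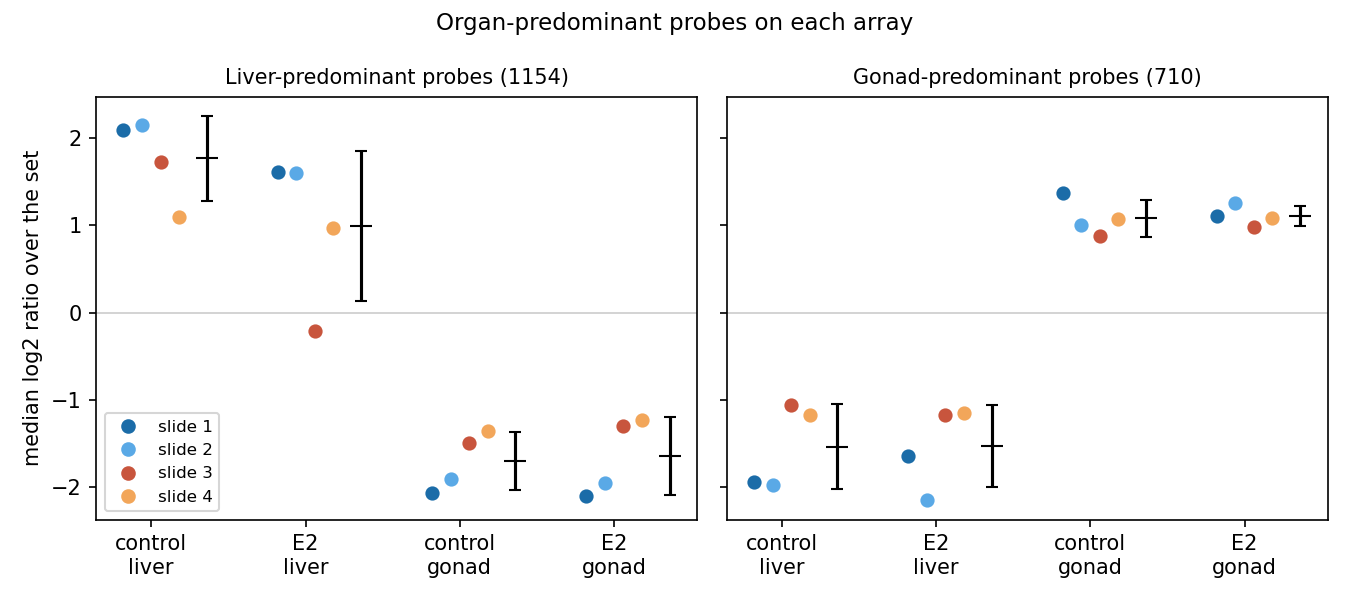
Median log2 ratio of 1154 liver-predominant probes (left) and 710 gonad-predominant probes (right) on each array, by group. Points are arrays coloured by slide, horizontal marks are group means and bars are SD. Among livers, E2 liver 3 has the lowest liver-predominant median at -0.21.

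In gonad, no probe passed the threshold for E2 against control. The count was 0 of 19044 probes tested (limma, n = 4 per group), with 260 at an unadjusted p under 0.05 (1.37%) against 952 expected by chance. At the median probe the 95% interval reached 0.39 to either side on the log2 scale, and 94.7% of probes had an interval that lay within a 2-fold change in either direction. The reported fit has no slide term, so differences between slides are part of the residual spread behind these counts and intervals. With the slide as a block, 0 probes passed and 526 had an unadjusted p under 0.05 (limma). These intervals limit the ratios of the reported fit only. Sizes could be larger with another background correction, as at UF_Msa_CM_133357 below, so larger changes of transcripts are not excluded. The sign was the same on all 4 slides at 9.43% of probes, against 12.5% by chance. The processed signals gave 2 probes lower in E2 gonad, UF_Msa_CF_120210 and UF_Msa_CM_133357. Offset 0 gave UF_Msa_CF_120210 alone and the value table UF_Msa_CM_133357 alone. The fit without control gonad 2 gave 1 probe.

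In the reported fit, the probes with the smallest raw p in gonad all had a limma adjusted p of 1.00. UF_Msa_AF_100201 (contig16807) had a log2 change of 0.82 ± 0.16 (SE) and UF_Msa_CM_132623 (contig19950) of 0.78 ± 0.16. UF_Msa_CM_133357 (contig13915) had a log2 change of -1.29 ± 0.28, while another probe of its contig had 0.09. UF_Msa_CF_120210 was well above background on 3 of the 4 control gonads and not well above background on any E2 gonad. The bound from its group means was a signal 2.14-fold lower in E2 gonad. This bound carries no error, and the probe did not pass the threshold in the reported fit. It passed with the processed signals (limma adjusted p = 0.0382) and with offset 0 (limma adjusted p = 0.0114), calls that rest on E2 values at background, for which no size is given. UF_Msa_CM_133357, well above background on 2 of the 4 E2 gonads, had a log2 change of -3.48 with the processed signals (limma adjusted p = 0.0328) and -3.32 in the value table (limma adjusted p = 0.0314). Within slides the log2 changes ranged from 0.34 to 1.01 at UF_Msa_AF_100201, from 0.53 to 1.16 at UF_Msa_CM_132623 and from -2.41 to -0.44 at UF_Msa_CM_133357. In gonad, liver-predominant probes differed by 0.06 (exact permutation p = 0.743, n = 4) and gonad-predominant probes by 0.03 (exact permutation p = 0.80, n = 4).

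**Figure D3:**
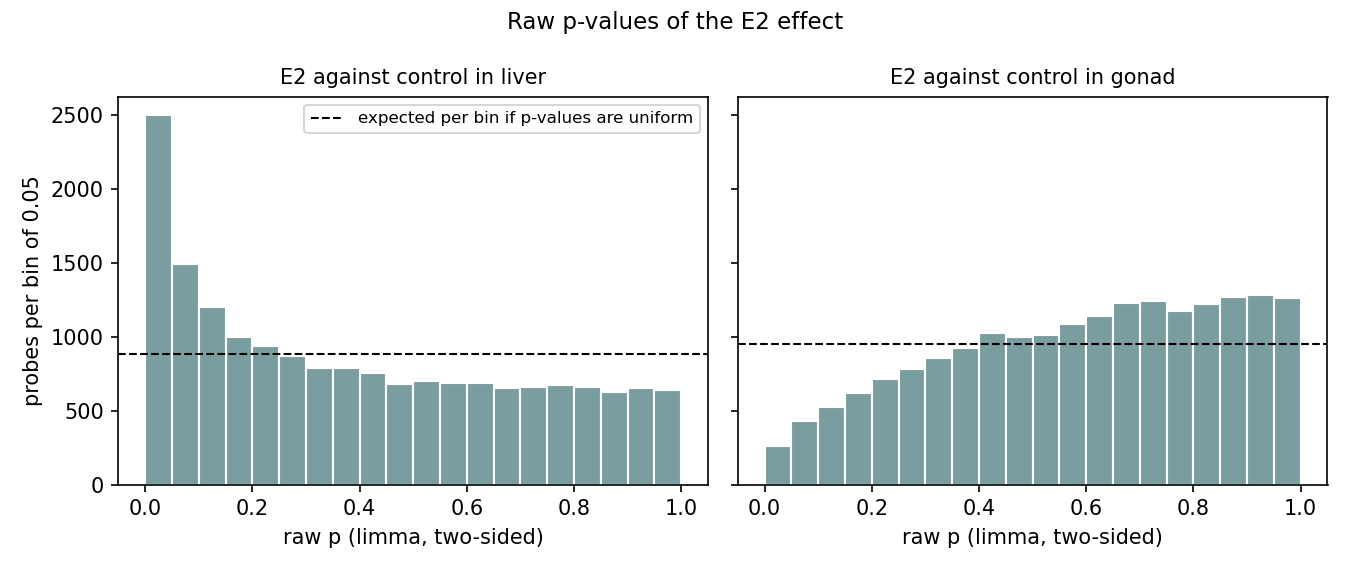
Probes per bin of unadjusted p (limma, bin width 0.05) for E2 against control in liver (left) and gonad (right). The dashed line is the number per bin if p-values were uniform, 883 in liver and 952 in gonad. The first bin held 2500 probes in liver and 260 in gonad.

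The E2 effect differed between the organs at 1 of 20249 probes (limma interaction, 0 higher and 1 lower in liver). UF_Msa_AM_116619 had an E2 effect in liver that lay below that in gonad by a log2 difference of -2.80 ± 0.37 (SE, interval -3.59 to -2.01, limma adjusted p = 0.0248). Its gonad means were 1.58 ± 0.28 in control and 1.67 ± 0.52 in E2 (SD, n = 4). On slides 1 to 4 the difference was -3.46, -1.78, -2.90 and -3.06. At an unadjusted p under 0.05 there were 2105 probes (10.4%). UF_Msa_AF_109886 was not tested for the difference, because its spots were marked on too many gonad arrays.

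With the slide as a block, 2 probes passed for the difference between organs, 1 in each direction. UF_Msa_AM_116619 then had a limma adjusted p of 0.0107. UF_Msa_AF_102449 differed by 1.94 ± 0.38 (SE), with a limma adjusted p of 0.259 without the block and 0.00668 with it. It was well above background on only 2 of 4 arrays in each gonad group, and its difference was 3.73 with the processed signals, 3.52 in the value table and 1.28 with median centring, so its size is uncertain. On slides 1 to 4 its difference was 2.16, 2.08, 1.71 and 1.83. UF_Msa_CM_135824 differed by -2.15 ± 0.36 (limma adjusted p = 0.215) and UF_Msa_CF_122270 by 1.47 ± 0.29 (limma adjusted p = 0.259), neither past the threshold. The count was 1006 with array quality weights, 223 without control liver 4 (44 higher and 179 lower), 98 without E2 liver 3 (75 higher and 23 lower) and 46 without E2 liver 2 (5 higher and 41 lower). Median centring, Cy5 alone, no filter, and trend and robust each gave 0. Across the 16406 probes tested in both organs, E2 effects in liver and gonad correlated at r = -0.05. Gonad effects themselves correlated at only -0.024 between slides 1 and 2 and slides 3 and 4, so that value does not show whether the organs respond alike. The shift of liver-predominant probes differed between organs by -0.83 (permutation p = 0.163, all 4900 arrangements).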

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

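The splits of the arrays for the difference between organs and between the control organs were set before their results were seen. The arrangements within slides, the treatment of marked spots, the fits on slides 1 and 2 or 3 and 4 alone and the exclusion of a pair of arrays were chosen after. UF_Msa_AM_116619 stood out because its E2 effect differed between liver and gonad, by -2.80 on the log2 scale. The direction held in all 36 alternatives of that result, from -3.16 to -2.42, and 15 of them no longer passed the threshold. When E2 and control labels were exchanged at random within each organ, 11 of 100 arrangements gave at least 1 probe, the real one included, and the highest other gave 779. Because same-numbered arrays share a slide, labels were also exchanged only within slides, in 100 of the 128 possible arrangements. There 11 gave at least 1 probe (highest other 3), and with the slide as a block 12 gave at least the real 2 (highest other 3). Some of these arrangements exchanged labels in gonad only and so kept the whole liver effect. The probe changed in liver and hardly in gonad, so such arrangements reach the real count almost by construction. These shares could therefore hardly be low, and the counts cannot exclude chance. The probe itself had a limma adjusted p of 0.0107 with the block (range 0.00270 to 1.00 over the alternatives). The probe belongs to the class named minus, and the other probes of its contig gave differences of -0.27 and -0.24. The E2 exposure is a biological explanation that the design names, and no technical explanation was tested for this probe.

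No array stood apart from the other 3 of its group by the test of the gap to the nearest value. Of 42 groups of 4 values examined, 0 were found, where chance would give 2.1. Among 4 values that test finds only very wide gaps, so it does not show that the arrays were alike. It did not find E2 liver 3, which had the lowest liver-predominant median and is described below.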

How the results depend on the processing

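The alternatives on marked spots, on slides 1 and 2 or 3 and 4 alone, on E2 liver 3 and control gonad 3 left out together, and all those of the liver-predominant shift were chosen after the data were seen. For E2 in liver (2 probes), the slide block gave 0, median centring 0, no filter 0, slides 1 and 2 alone 0 and slides 3 and 4 alone 0 (limma, 2500 at an unadjusted p under 0.05 in the reported fit). No background subtraction, the value table, the mean over a contig name, marked spots kept in the background fit and marked spots kept in the averages gave 1 each. All 16 arrays in 1 fit gave 721 and array quality weights 1296, where control liver 1 and 2 had weights of 2.97 and 3.88 and E2 liver 3 had 0.424. Leaving out 1 replicate gave 0 to 142. The first run gave 2. For E2 in gonad (0 probes), processed signals gave 2, offset 0 gave 1, the deposited table also 1, and replicates left out 0 to 1. The first run gave 0, with 109 at an unadjusted p under 0.05.

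For the difference between organs (1 probe), processed signals, offset 0, the value table, the replicate block and the first run gave 2 each. Median centring, Cy5 alone, no filter, trend and robust, and slides 3 and 4 alone gave 0. Slides 1 and 2 alone gave 6, array quality weights 1006, and E2 liver 3 and control gonad 3 left out together 21. Replicates left out gave 0 to 223, with 0 without control liver 3, control gonad 2, 3 or 4, E2 liver 1 or 4, or E2 gonad 1, 3 or 4. Taking same-numbered liver and gonad as 1 fish, which the labels do not state, a random block (correlation 0.0879) gave 1. For the control organs (11398 probes), median centring gave 5691 and slides 3 and 4 alone 7029. The first run gave 8373 and replicates left out gave 9939 to 11515. Apart from the fits on fewer arrays, the cause was not tested.

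UF_Msa_AF_109886 rose by 4.31 to 6.58 in 24 alternatives, 12 of them past the threshold. UF_Msa_AM_116619 fell in liver in 27 alternatives, between -3.06 and -2.48, 18 past the threshold. No named probe changed sign, while the balance of higher to lower probes between the control organs turned with the scaling, from 59.8% higher to 25.1% with median centring. The liver-predominant shift in liver lay between -1.0 and -0.37 in 19 alternatives. The shifts near 0 did change sign: that of gonad-predominant probes in liver with marked spots kept in the background fit and in the first run, and those of both sets in gonad with median centring. The liver-predominant difference within slide 4 also changed sign, with median centring and with Cy5 alone. The block changed no call other than those given in the report, and for the control organs, whose numbers did not pair by the rule, it gave 11748. Aquantile after loess leaves ratios as they are, so it tests nothing here. The list tests (camera, fry, estimated correlation) and the scan-day block were not run. Cy5 signal over background limits slides 3 and 4 most, where 49.7% to 60.8% of spots were well above background.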

Other observations

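The tests of E2 liver 3, of the changes shared between slides, of single-spot defects and the splits of the E2 comparisons within each organ were chosen after their results were seen, except the split of the processed signals. Probes of the 4 classes differed in how often they gave signal. Above background were, on average per array, 84.7% of AF probes, 56.6% of CF probes, 48.5% of CM probes and 37.1% of AM probes. The organ difference was seen in every class, at 61.2% of the tested AF probes, 56.0% of CF, 54.0% of CM and 54.5% of AM. The classes named minus thus gave both signal and organ differences, and whether their transcripts run in the opposite direction to the contigs was not tested.

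For the low liver-predominant signal of E2 liver 3, gonad RNA in the sample would need a share of 70.1% to lower these probes by the observed -1.74. That share would raise gonad-predominant probes by 2.18, but they lay only 0.42 above the other livers. Relative to the control liver of its slide they lay at -0.11 in the reported fit. The sign of that value depended on the scaling, since with the processed signals their median was -1.99 on E2 liver 3 and -2.38 on control liver 3. E2 liver 3 correlated with gonads at 0.487 to 0.564, above the other livers (at most 0.385). Liver-predominant probes that are low for any reason can raise that correlation, so it does not decide on gonad RNA. A smaller share of gonad RNA stays open. A dimmer scan of its slide is argued against by the control liver of that slide, relative to which it lay at -1.79. An exchanged label with a gonad is argued against by its correlations, at least 0.655 with other livers. A stronger response of this fish to E2, or another state of the fish, stays open and was not tested.

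UF_Msa_AF_109886 also had a low signal of the Cy3 reference where its Cy5 signal was highest. All 6 spots on E2 liver 1, 2 and 4 had Cy3 signals of at most 93160, below the lowest of the other arrays, 196737, which argues against defects of single spots. Competition of abundant Cy5 target with the reference may contribute: among 639 bright probes of other contigs, the liver minus gonad difference in Cy3 fell as that in Cy5 rose (slope -0.105 ± 0.0044 SE, r = -0.684 across probes). At UF_Msa_AF_109886 the Cy3 change per unit of Cy5 change was steeper on slides 1, 2 and 4 (-0.44, -0.50 and -0.25) and shallower on slide 3 (-0.06, at a Cy5 change of 2.01), so its size stays open. With Cy5 alone the log2 change was 4.40 (limma adjusted p = 0.0271, range 0.00924 to 0.453 over the alternatives), and no biological explanation was tested for the Cy3 signal.

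Fold changes in liver were shared between most slides although few probes passed, with r from 0.258 to 0.492 in 5 of 6 pairs of slides and -0.011 for slides 3 and 4. E2 liver 3 alone is argued against as their cause by the pairs of slides that do not hold it. Slides 1 and 2 correlated at 0.445, slides 1 and 4 at 0.492 and slides 2 and 4 at 0.258. Without E2 liver 3, 17.8% of probes (3141) had an unadjusted p under 0.05. That share can rise when a deviating array is left out, so it adds little. Sharing was not confined to slides of like Cy5 brightness, since means over the brighter and the dimmer slides correlated at 0.606. That value is part of the pattern itself and had been seen, so it does not decide whether brightness contributed. The E2 exposure, which the design names, stays open as a biological explanation and was not tested apart from the splits of the arrays.

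Of the 35 splits of the 8 livers, 3 gave at least the real 2 probes, and the highest other, 1028, set slides 1 and 2 against slides 3 and 4. For probes at an unadjusted p under 0.05, 3 of 35 splits gave at least the real 2500, and the highest other gave 4302. With the processed signals, 1 of 35 gave the real 3411, the highest other being 3040. Because the arrays were taken as paired by number, the real split is set beside the 8 splits that part every slide, which are too few for a share under 0.05. Among these, the highest other gave 0 probes past the threshold (limma), 1140 at an unadjusted p under 0.05, and 1445 at that level with the processed signals. The other splits keep both livers of at least 1 slide together.

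In gonad the real count was 0 (limma, 260 at an unadjusted p under 0.05), which all 35 splits reach by construction, so the splits say nothing about it. The split of slides 1 and 2 from slides 3 and 4 gave 3446. With the slide as a block the count was 0, with 526 at an unadjusted p under 0.05. The first principal component of the gonad arrays (44.7% of variance, 26.8% with the processed signals and 84.0% with median centring) was above 0 on slides 1 and 2 and below 0 on slides 3 and 4, a structure of the arrays that follows the slides in the reported fit. With the processed signals control gonad 3 lay on the same side as control gonad 1 (0.06 and 0.10), so the parting by slide depends on the scaling. Before loess, the median log ratio of bright spots lay below that of dim spots by -3.52 to -1.98 on slides 3 and 4, against -1.17 to 0.46 on slides 1 and 2.

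For the control organs, 1 of 35 splits gave as many as the real 11398, the smallest share that these splits allow, and the highest other gave 2. Among the 8 splits that part every slide, too few for a share under 0.05, the highest other gave 1. These values argue against chance as the source of that count.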
